A study of Mus musculus with 8 samples.

How the data were processed

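Gene expression was measured in injured carotid arteries of ApoE-/- mice, in 4 mice with miR-126 (miR-126+/+) and 4 mice without it (miR-126-/-). Per the labels, the mice were female, 6 weeks old, of mixed genetic background and fed a western-type diet, and the arteries were taken 14 days after wire injury. Per the labels' protocols, RNA was isolated with an RNeasy micro kit, and 100 ng of total RNA with spike-in controls was labelled with Cy3 and hybridised to Agilent mouse arrays with 8 arrays on a slide. Per the file headers, the arrays were read in a single colour with Agilent Feature Extraction 10.7.3.1, and the values used are processed signals, which are intensity values on a linear scale after background subtraction. The authors' deposited value table holds the same intensity values, linear and not scaled between arrays. Its median log2 difference from the scanner signal was 0 on each array, and over 99.9% of probes lay within 0.1 log2 units. Its column medians ran from 41.4 to 57.0.

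Each array held 62976 spots, of which 59305 were not controls, for 55681 probes. Control spots and spots that the scanner software marked as outliers (146 to 216 per array) were left out, and spots of the same probe were averaged. The main values are log2 of the processed signal minus the array's 75th percentile of that signal. A probe entered when it was well above background on at least 3 of the 4 arrays of a genotype, which 32484 probes did. Each gene was represented by its probe with the highest mean signal, so that 23830 genes or transcripts were tested. Splice forms and low-signal probes of the same gene therefore do not enter the main values. Probes were named through their RefSeq accession where the table of RefSeq genes (assembly GRCm38.p6, used for names only) held it, which was so for 26413 probes (47.4%), and the symbol of 3093 probes changed by this step. The other probes kept the name in the file. Positions are those of the files, on mouse build mm9, per the file headers.

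Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, 6 residual degrees of freedom), with two-sided p-values adjusted by the Benjamini-Hochberg method over all genes tested and a threshold of 0.05. Genes with an unadjusted p under 0.01 and a fitted difference of at least 2-fold were counted as a description. A set of 24 gene lists, of at least 5 tested genes each, was tested with limma's camera at a preset inter-gene correlation of 0.01, and the adjustment ran over the 24 lists. Each list was also tested with an estimated correlation and with limma's fry, and its mean per array (each gene centred over the 8 arrays) by an exact permutation test over the 70 arrangements of the arrays, two-sided. Genes near the targeted locus were compared with other genes by Fisher's exact test, two-sided. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served to read the files and draw the figures.

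The genotype comparison, the gene lists, the tests, the rule for naming genes and the list of alternatives were fixed before the data were examined. The rule names Egfl7 and Apoe, and in each direction the 12 genes with the largest difference among those past the adjusted threshold without overlap of the genotypes. Names that are clone, predicted, transcript or chromosome region identifiers were left out. Places left open were filled with genes of at least 2-fold fitted difference and no overlap by smallest unadjusted p, given as values that did not pass. It also names up to 4 members of each list with the smallest unadjusted p, reported miR-126 targets that pass, and Dlk1, Spred1, Pik3r2 and Vcam1 in any case. Some genes that the rule names are not reported here. Genes named outside this rule for their values, among them Cfd, Fabp4, Sdha, Vcl, Synpo2 and Mylk, were chosen after these values were seen.

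The alternatives were normexp background correction with an offset of 50, quantile normalization, the 75th percentile over probes above background on all arrays, the deposited table, no filter or a stricter filter on dim probes, the mean of a gene's probes, every probe on its own, an intensity trend, array weights, the replicate number as a block, the skeletal muscle or adipocyte list mean as a covariate, other set tests, other windows around the locus, and each array left out in turn. A further 3 alternatives were chosen after seeing the data: without the array of each genotype least similar to its own group, without the 2 arrays highest in skeletal muscle genes, and without the spots of a dim area on array miR-126-/- 4. For a gene not well above background on any array of a genotype, the difference is given as "at least N-fold". This bound sets the brighter genotype's mean against the dim genotype's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background.

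The fit and the list test were tested on simulated data made from the 23830 genes, in 5 runs with 200 changed genes each. The fit recovered 63.4% of genes changed by 1 log2 unit and 88.8% of genes changed by 2 log2 units, with a mean of 8.8 unchanged genes called per run. A list shifted by 0.5 log2 units was found in 5 of 5 runs, and 0 other lists were called. The simulated genes varied independently, which genes on the arrays do not: each of the 34 other splits of the 8 arrays into 4 and 4 gave 3 to 13 called lists. The number of arrays limits the precision of every value. Predicted miR-126 sites in transcripts were not analysed here.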

Results

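Wire injury strips the endothelium from an artery and is followed by growth of a neointima, a new inner layer rich in smooth muscle cells. Gene expression was measured 14 days after such injury in carotid arteries of ApoE-/- mice, which lack apolipoprotein E and develop high plasma cholesterol. The comparison asks how loss of miR-126, a microRNA enriched in endothelial cells, alters the transcripts of the injured artery, and it sets 4 miR-126-/- mice against 4 miR-126+/+ mice with 1 array per mouse. Between 55.9% and 61.5% of the 55681 probes were well above background, the array's 75th percentile of signal lay between 619.7 and 864.6 intensity units, and 0 spots were saturated. Correlations between arrays ran from 0.959 to 0.987. All 8 arrays lay on 1 slide read in 1 scan. The miR-126+/+ arrays filled slide row 1 and the miR-126-/- arrays slide row 2, so slide row and genotype cannot be told apart. The scanner software's measure of spatial trend ran from 2.05 to 2.25 on miR-126+/+ arrays and from 2.35 to 3.04 on miR-126-/- arrays. Whether this bears on the comparison was not tested. Array miR-126-/- 4 held a local dim area. Of its 97 bright spots that lay at least 2 log2 units below every other array, 94 were between grid row 55 and 100 and between grid column 56 and 70, an area that held spots of 235 tested genes, among them Hoxb8, Sdha, Vcl, Synpo2 and Mylk.

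**Figure D1:**
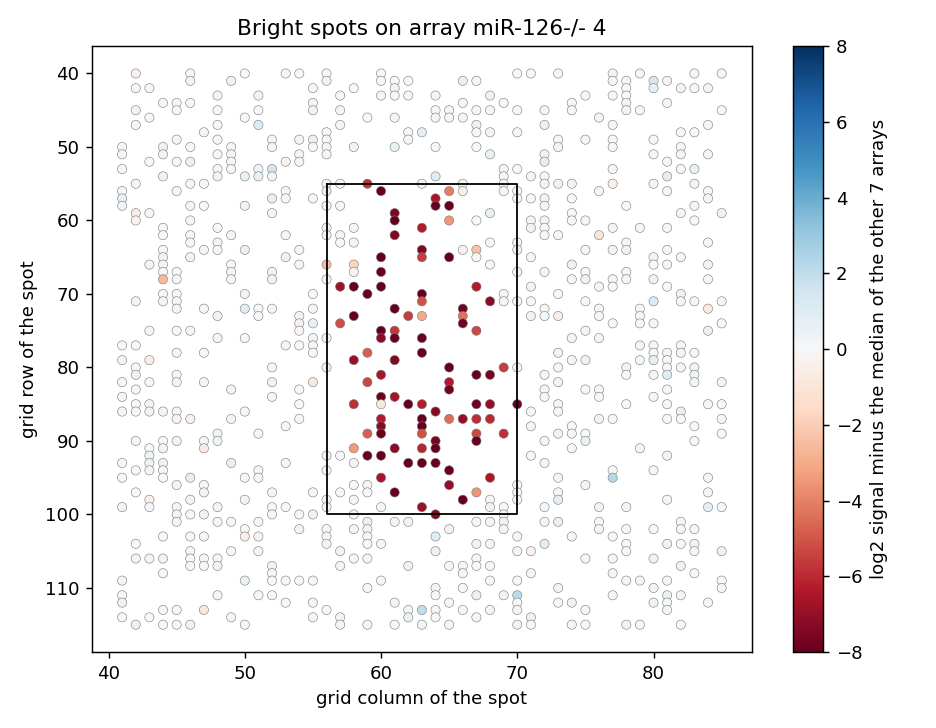
Position of bright spots on array miR-126-/- 4 by grid row and grid column, coloured by their log2 signal minus the median of the other 7 arrays. Inside the drawn rectangle lie 94 of the 97 spots that were at least 2 log2 units below every other array.

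Egfl7, an endothelial gene whose intron holds miR-126, had a log2 signal (relative to the array's 75th percentile) of 6.51 ± 0.19 (SD, n = 4) in miR-126-/- arteries and 6.01 ± 0.17 (SD, n = 4) in miR-126+/+ arteries. The difference of 0.49 ± 0.13 (SE) did not pass the test over all genes (adjusted p = 0.256), although all 4 miR-126-/- values lay above all 4 miR-126+/+ values. Apoe, which is disrupted in both genotypes, gave 2.62 ± 0.27 against 2.0 ± 0.54 (SD, n = 4 each; difference 0.63 ± 0.27, adjusted p = 0.492). No probe used here is named for miR-126 itself. The Apoe probe was well above background on all 8 arrays. Neither this probe nor the Egfl7 probe (chromosome 2, 26448142 to 26448201, mm9) is known to lie in the disrupted part of its gene, and a probe outside that part checks nothing about the label.

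In miR-126-/- arteries 13 genes or transcripts rose and 10 fell, out of 23830 tested. The neighbouring homeobox genes Hoxb7 and Hoxb8, which specify position along the body axis, were not well above background on any miR-126+/+ array and were at least 5.63-fold and at least 1.82-fold higher in miR-126-/- arteries. Card9, an adaptor of innate immune signalling, rose 4.53-fold, Pebp1, a Raf kinase inhibitor protein, rose 2.18-fold, and Tob1, an antiproliferative protein, rose 1.81-fold. Med16, a subunit of the Mediator complex, fell by 1.73 log2 units (3.31-fold), and the agouti coat colour gene a was at least 1.80-fold lower and not well above background on any miR-126-/- array. Each value is that of the gene's brightest probe, and second probes of Pebp1 and Med16 differed by only 0.02 and 0.10 log2 units.

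The fitted differences (miR-126-/- minus miR-126+/+, log2 ± SE, n = 4 each) were 2.18 ± 0.20 for Card9 (adjusted p = 0.0207) and -1.73 ± 0.11 for Med16 (adjusted p = 0.00942). Hoxb7 had an adjusted p of 0.0208 and Hoxb8, well above background on 3 of 4 miR-126-/- arrays, of 0.04998. The spot of Hoxb8 lay in the dim area of miR-126-/- 4, and without the spots of that area its adjusted p was 0.0119 (0.0119 to 0.823 over its alternatives). Casp14, a caspase of keratinised epithelium, was not well above background in miR-126+/+ arteries and was at least 2.59-fold higher (adjusted p = 0.0164). Ifi27l2b rose by 1.31 ± 0.14 and Pebp1 by 1.12 ± 0.12 (adjusted p = 0.0351 each), while agouti and the endophilin gene Sh3gl3 (-0.94 ± 0.10) had an adjusted p of 0.0331 each. The other named genes shared with Hoxb8 the highest adjusted p among the called genes, 0.04998: Msmp (1.99), Lctl (1.59), Krtap1-4 (at least 1.62-fold), Magix (1.35) and Tob1 (0.86) were higher, and Fam228a (at least 2.08-fold), Baiap2l2 (-1.89) and Cercam (-1.08) were lower. The remaining 6 of the 23 were chromosome regions or a transcript without a symbol. Probes of a gene did not always move together. A second Med16 probe differed by 0.10 ± 0.08 and a second Pebp1 probe by 0.02 ± 0.08, and second probes of Ifi27l2b and Magix differed by 0.22 and 0.81. Genes next in order did not pass: Lhx3, a homeobox gene not well above background in miR-126+/+ arteries, was at least 2.10-fold higher (adjusted p = 0.0517), and Vmn1r204 (-1.88, adjusted p = 0.0577), Tll1 (-1.10 ± 0.17, adjusted p = 0.0749), B3gnt6 (at least 1.56-fold lower, adjusted p = 0.0785), Hoxd11 (at least 1.68-fold lower, adjusted p = 0.137) and Shank1 (-1.55, adjusted p = 0.149) were lower. The other tested probes of Shank1 gave 0.34 ± 0.28 and -0.01 ± 0.11, so the gene was clearly lower by its brightest probe alone. A second Tll1 probe gave -0.41 ± 0.10.

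**Figure D2:**
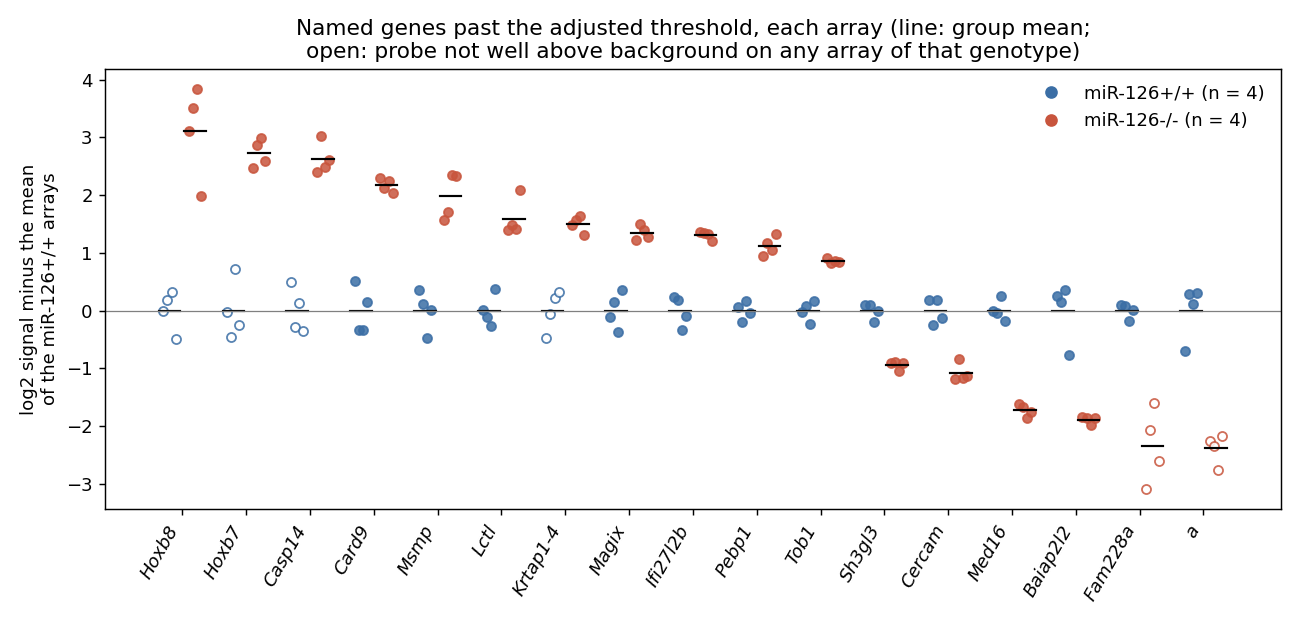
Log2 signal of 17 named genes that passed the test, per array, minus the gene's mean over the 4 miR-126+/+ arrays, with lines at the mean of each genotype and open symbols where the probe was not well above background on any array of that genotype, so that only a bound is known. By the naming rule the genotypes do not overlap for any of the 17, among them Card9 (2.18) and Med16 (-1.73).

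For all 23 called genes and transcripts the genotypes did not overlap, as was so for 6.29% of all genes tested, where chance gives 2.86%. An unadjusted p under 0.05 was found for 2426 genes (10.2%), against 1191.5 by chance. Both values were higher in 2 other splits of the 8 arrays into 4 and 4 (6.67% and 6.53% of genes without overlap, 2760 and 2548 genes at an unadjusted p under 0.05). In all, 276 genes had a fitted difference of at least 2-fold with an unadjusted p under 0.01, 203 of them higher and 73 lower in miR-126-/- arteries. This count includes genes dim in 1 genotype, whose fitted differences are not measured sizes, such as Hoxb8 (known only as at least 1.82-fold). The number of called genes rested on single arrays: it was 6, 3, 11 and 59 without miR-126+/+ 1, 2, 3 and 4, and 5, 0, 4 and 15 without miR-126-/- 1, 2, 3 and 4, where limma gave 1898 genes at an unadjusted p under 0.05 without miR-126-/- 2. It was 5 with the skeletal muscle list as a covariate, and limma gave 0 with the adipocyte list as a covariate (1005 genes at an unadjusted p under 0.05) and 0 without miR-126+/+ 2 and miR-126-/- 1 together (2047 such genes).

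Reported targets of miR-126 went both ways. Of 30 listed, 29 were tested (Mmp7 was not), 15 were higher and 14 lower in miR-126-/- arteries, and the median difference was 0.03. Dlk1, a non-canonical Notch ligand reported as a target of the miR-126 passenger strand, was 2.01-fold higher (0.87 ± 0.34 against -0.14 ± 0.33, SD, n = 4 each), with all 4 values above those of miR-126+/+ arteries. Ptpn7, a tyrosine phosphatase, gave -0.51 ± 0.10. Spred1 (-0.13 ± 0.09), Pik3r2 (0.15 ± 0.14) and Vcam1 (0.35 ± 0.20), targets known from endothelial cells, differed by at most 2 standard errors.

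Over all genes, 0 of the 29 targets passed in limma, and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 1 was higher (Dlk1, adjusted p over all genes = 0.182) and 1 lower (Ptpn7, adjusted p over all genes = 0.169). Dlk1 was reported as a target in work on this mouse model, so its place on the list is not independent evidence. A second Dlk1 probe gave 0.69, and second probes of Ptpn7 and Vcam1 gave 0.13 and -0.01. A second Spred1 probe gave -1.76 ± 1.40, and -0.15 ± 0.12 without its spot on miR-126-/- 4, which lay in the dim area. Adm, the vasodilator adrenomedullin, gave 0.67 ± 0.18 (adjusted p = 0.256) and Rgs16 -0.38 ± 0.13 (adjusted p = 0.367). The list test gave an adjusted p of 0.659, and 0.920 with an estimated correlation.

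Genes of the Notch pathway were higher on average in miR-126-/- arteries. Of 30 tested, 21 were higher and 9 lower, with a median difference of 0.10 and a mean of 0.17. The ligand gene Dll1 gave 0.66 ± 0.13, the feedback inhibitor gene Nrarp 0.83 ± 0.17 and the fringe gene Mfng 0.43 ± 0.12 (SE, n = 4 each). The list passed in camera (adjusted p = 0.0490; adjusted p = 0.837 with an estimated correlation). Over all genes 0 members passed in limma, where 7 had an unadjusted p under 0.05. Adjusted over the list alone, 3 were higher (Dll1, Nrarp and Dlk1). The list mean per array lay above 0 in all 4 miR-126-/- arteries and at most at 0.0042 in miR-126+/+ arteries (exact permutation p = 0.0286, the smallest that 70 arrangements can give). After adjustment over 24 lists it was 0.229, and it could have passed only if most lists had reached that smallest value. The list passed in 13 of 26 alternatives (adjusted p from 0.00598 to 0.837), and leaving out miR-126+/+ 1, miR-126+/+ 3, miR-126-/- 2 or miR-126-/- 4 gave 0.0590, 0.199, 0.0705 and 0.0506. With the adipocyte list mean as a covariate, the Notch mean went from 0.17 to 0.081 and its call was lost (adjusted p = 0.456).

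Adipocyte genes stood higher in miR-126-/- arteries by more than any other list. All 29 tested members were higher, with a median difference of 1.36 and a mean of 1.30. The water and glycerol channel gene Aqp7 gave 1.31 ± 0.26, the resistin gene Retn 1.38 ± 0.30, Thrsp, a regulator of lipid synthesis, 1.85 ± 0.41, and the carbonic anhydrase gene Car3 1.28 ± 0.28 (SE, n = 4 each). The abundant fat transcripts Cfd and Fabp4, chosen after their values were seen, had mean log2 signals of 8.22 and 7.97 in miR-126-/- arteries, against 7.22 and 6.94 in miR-126+/+ arteries. On the adipocyte list 1 member (Lpl) also stands on another list. Genes of mitochondrial oxidative phosphorylation were higher too, by a smaller amount: 33 of 34 were higher with a median of 0.36, among them the complex I subunit genes Ndufa5 (0.40 ± 0.10), Ndufab1 (0.43 ± 0.11) and Ndufb9 (0.41 ± 0.11) and the complex III subunit gene Uqcrc1 (0.52 ± 0.14). The exception was Sdha (-1.25 ± 1.34), whose spot lay in the dim area of miR-126-/- 4. Endothelial genes were higher for 28 of 30 members, with a median of 0.28, led by Gpihbp1, which carries lipoprotein lipase in capillaries (1.73 ± 0.24), and by Adgrl4 (0.92 ± 0.15), Tal1 (0.74 ± 0.14) and Cldn5 (0.48 ± 0.14).

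The adipocyte list passed in camera (adjusted p = 2.16e-21; adjusted p = 0.762 with an estimated correlation), as did oxidative phosphorylation (adjusted p = 3.21e-16; adjusted p = 0.762 with an estimated correlation) and the endothelial list (adjusted p = 3.21e-08; adjusted p = 0.837 with an estimated correlation). Over all genes 0 members of these lists passed in limma, where 26, 22 and 10 had an unadjusted p under 0.05. Adjusted over the list alone, 26 adipocyte, 19 oxidative phosphorylation and 3 endothelial genes (Gpihbp1, Adgrl4 and Tal1) were higher and 0 were lower. The list mean per array was 0.65 ± 0.36 against -0.65 ± 0.62 (SD, n = 4 each) for adipocyte genes and 0.15 ± 0.15 against -0.15 ± 0.11 for oxidative phosphorylation (exact permutation p = 0.0286 each, two-sided; 0.229 adjusted over 24 lists), and 0.15 ± 0.16 against -0.15 ± 0.12 for endothelial genes (exact permutation p = 0.0571; adjusted 0.274). No smaller p than 0.0286 is possible with 70 arrangements, so an adjusted value could pass only if most lists reached it. Of 24 lists, 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) and 0 with fry (4 at an unadjusted p under 0.05), where camera called 4. With the adipocyte list mean as a covariate, the mean difference of oxidative phosphorylation went from 0.31 to 0.079 and its call was lost.

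**Figure D3:**
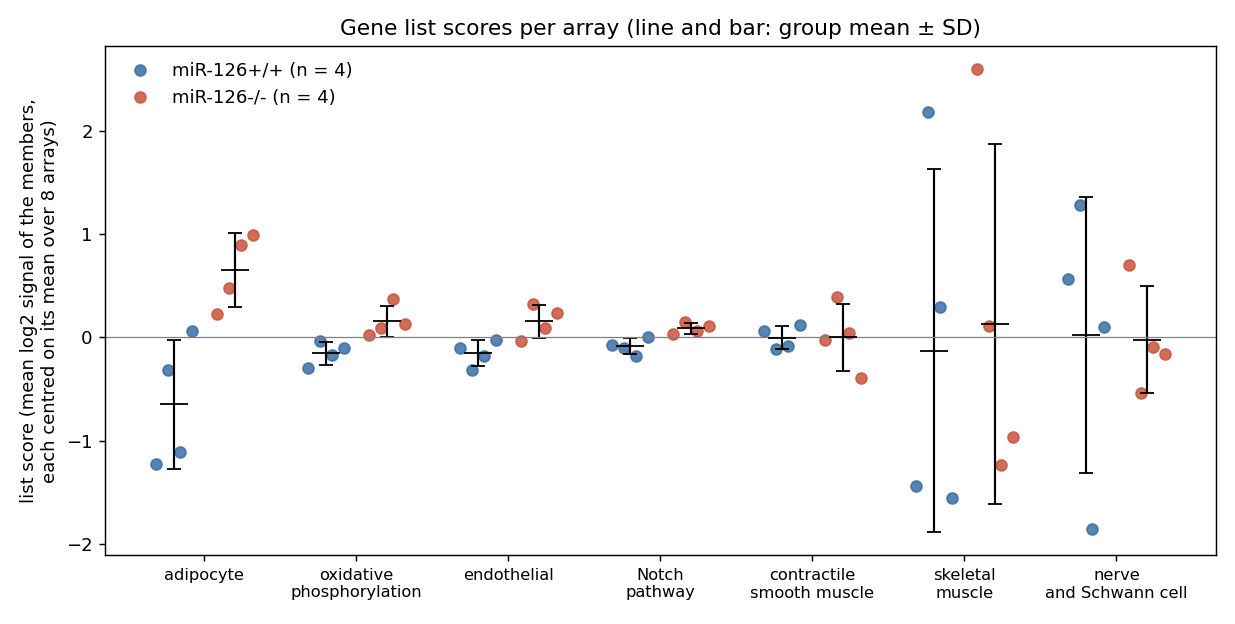
Mean of 7 gene lists per array (log2, each gene centred over the 8 arrays), with the mean ± SD of each genotype. The adipocyte, oxidative phosphorylation and Notch means do not overlap between genotypes, while the skeletal muscle mean is 2.19 on miR-126+/+ 2 and 2.60 on miR-126-/- 1 and at most 0.30 elsewhere.

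Smooth muscle, matrix and immune cell genes did not pass as lists in the main setting. Of 30 contractile smooth muscle genes 21 were higher, with a median of 0.14 and a mean of 0.0057 (camera adjusted p = 0.162). Vcl, Synpo2 and Mylk had their spots in the dim area of miR-126-/- 4. Without the spots of that area the list's mean was 0.16. The list then passed in camera (adjusted p = 0.0414, and 0.0101 to 0.921 over its alternatives), which leaves out genes with a missing value and so these 3. With an estimated correlation the list gave an adjusted p of 0.920 in the main setting. It had not passed there at the preset correlation either, so this does not test the call without the dim area. Lmod1 gave 0.93 ± 0.36 and Smtn, Cnn1 and Rgs5 gave 0.37, 0.35 and 0.25. Of 33 extracellular matrix and fibroblast genes 18 were lower (median -0.05, adjusted p = 0.187), among them the proteoglycan gene Dcn (-0.83 ± 0.20) and Fn1 (-0.77), while Col3a1 gave 0.34 and Sparc -0.33. Matrix proteases and inhibitors (25 tested, median -0.08, adjusted p = 0.506) had 1 member, Adamts9 (0.50 ± 0.10), that passed adjusted over the list alone. Osteochondrogenic genes (24 tested, adjusted p = 0.714) had a median of 0.0094 and a mean of -0.042, with Msx2 at -0.57 and Bmp2 at 0.49. Of 29 macrophage genes 19 were lower (median -0.08, adjusted p = 0.187), with Lyz1 at -1.49 ± 0.54, Itgax at -0.45 and Cd36 at 0.63. Of 29 lymphocyte genes 21 were higher (median 0.32, adjusted p = 0.162), led by the immunoglobulin joining chain gene Jchain (2.31 ± 0.36), which passed adjusted over the list alone, and the B cell coactivator gene Pou2af1 (1.28 ± 0.36).

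Lists of inflammation, growth and stress did not pass either in the main setting. The adjusted p was 0.636 for neutrophil and platelet genes (7 of 21 higher), 0.659 for erythroid genes (4 of 9 higher), 0.527 for cytokines, chemokines and adhesion molecules (11 of 33 higher), 0.659 for cell cycle genes (24 of 32 higher, median 0.08), 0.229 for immediate early genes (8 of 23 higher), 0.659 for heat shock and stress genes (14 of 28 higher) and 0.659 for cholesterol and lipid handling (12 of 30 higher, with Srebf1 at 0.93 and Nr1h3 at 0.39). Interferon response genes (16 of 30 higher, adjusted p = 0.752) had a median of 0.022 and a mean of 0.041 where camera pointed down. Genes of ERK feedback and growth factor signalling (13 of 29 higher, adjusted p = 0.659) had a median of -0.02, a mean of 0.0081 and a test that pointed down, with Vegfa at 0.57 and Ccnd1 at -0.69. Glycolysis and hypoxia genes (17 of 29 higher, median 0.03) had an adjusted p of 0.506. With the adipocyte list mean as a covariate, 3 of these lists passed: interferon response (-0.144, adjusted p = 0.0134), cell cycle (0.379, adjusted p = 0.000504) and heat shock genes (0.263, adjusted p = 0.0391). These calls used camera's preset correlation. An estimated correlation was used in the main setting only, where it gave an adjusted p of 0.920 for each of the 3. They had not passed there at the preset correlation either, so this does not test the calls with the covariate.

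Genes of tissues next to the artery varied between mice of the same genotype. Skeletal muscle genes (20 of 27 higher, adjusted p = 0.714) had a list mean of 2.19 on miR-126+/+ 2 and 2.60 on miR-126-/- 1. Nerve and Schwann cell genes (12 of 30 higher, adjusted p = 0.506) had a list mean of -1.85 on miR-126+/+ 3 and 1.28 on miR-126+/+ 2. Thyroid, salivary gland and epithelium genes (13 of 17 higher, median 0.29) had an adjusted p of 0.162. Single arrays decided whether some of these lists passed: without miR-126+/+ 2 the matrix list (-0.21) and skeletal muscle (1.03) passed, without miR-126+/+ 3 lymphocyte (0.62), cell cycle (0.14) and nerve genes (-0.67), without miR-126-/- 1 contractile (0.016), lymphocyte (0.54) and skeletal muscle genes (-0.57), without miR-126-/- 2 lymphocyte (0.45) and immediate early genes (-0.14), and without miR-126-/- 3 macrophage genes (-0.19). With the adipocyte list mean as a covariate, skeletal muscle (1.45, adjusted p = 0.0263) and nerve genes (-0.67, adjusted p = 0.000427) passed. Other settings in which lists passed were no filter on dim probes (contractile and lymphocyte genes), array weights and the data without the least similar arrays (lymphocyte and nerve genes in each), and the data without the arrays highest in skeletal muscle genes (contractile and matrix genes). All of these calls used camera at its preset correlation.

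Card9, the called gene nearest to Egfl7, stood in a window whose share of genes with a low p-value did not differ past the test from that elsewhere. Within 5 Mb of Egfl7 on chromosome 2, 29 of 211 genes (13.7%) had an unadjusted p under 0.05, against 2396 of 23618 genes (10.1%) elsewhere. Card9 (chromosome 2, 26208462 to 26208521, mm9) and Lhx3 lay 0.240 and 0.392 Mb from Egfl7, Cercam lay 3.29 Mb away, and the Notch pathway gene Nrarp lay in the same window. A transcript without a symbol (0.90 ± 0.21) and Agpat2, a member of the adipocyte list (0.73 ± 0.29), lay 0.000468 and 0.000965 Mb from the Egfl7 probe. Neither passed in limma over all genes (adjusted p = 0.206 and 0.439). The odds ratio of 1.41 (95% interval 0.917 to 2.10) did not pass Fisher's exact test (p = 0.0866, two-sided), and windows of 1 Mb and 20 Mb gave 1.73 (p = 0.132) and 1.18 (p = 0.287). It passed under normexp background correction (1.57), the 75th percentile over probes above background on all arrays (1.52) and no filter on dim probes (1.74), and it was 0.894 with the adipocyte list as a covariate.

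**Figure D4:**
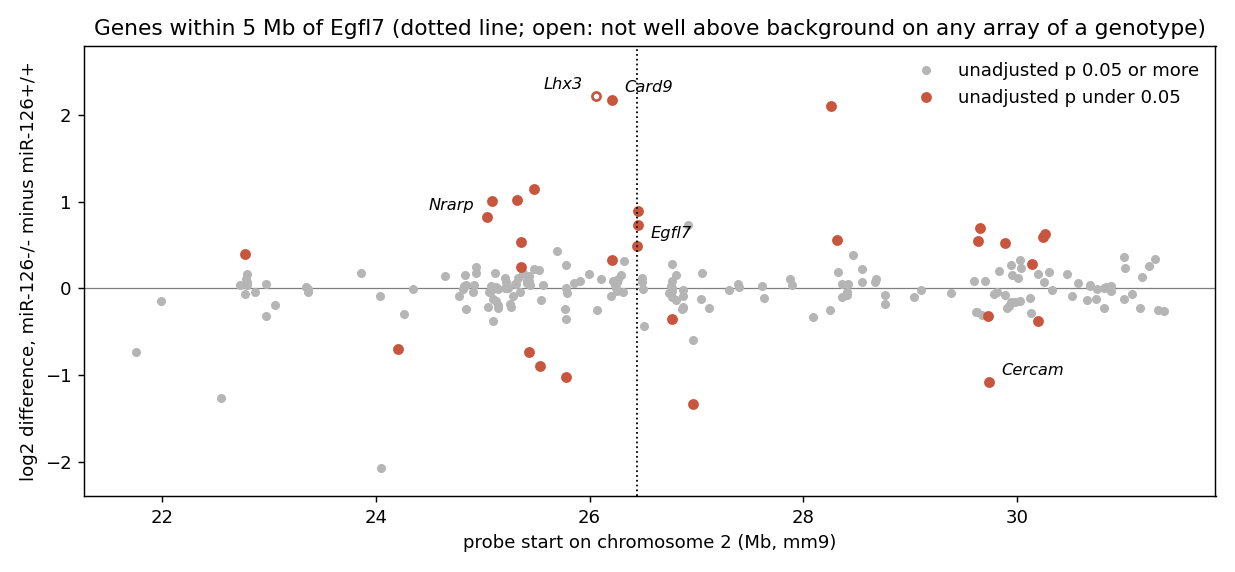
Log2 difference (miR-126-/- minus miR-126+/+) of genes within 5 Mb of Egfl7 against probe start on chromosome 2 (mm9), with genes at an unadjusted p under 0.05 in red and open symbols for probes not well above background on any array of a genotype. Card9, 0.240 Mb from Egfl7, differs by 2.18 and Cercam by -1.08, and Lhx3, 0.392 Mb away, has only a bound (at least 2.10-fold).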

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

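The tests of a common factor of the adipocyte genes, of random gene sets, of the genes at an unadjusted p under 0.05 over splits, of second probes and of the dim area, and the use of errors over mice in the tests with the adipocyte covariate, were chosen only after the results they bear on were seen. Of 290 groups of 4 values, 22 held a value far from the other 3, where chance gives about 14.5.

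On array miR-126+/+ 2, the log2 signal of Egfl7 was 5.76, against 6.07 to 6.13 on the other miR-126+/+ arrays. Array miR-126+/+ 3 stood apart for 6 genes: Tll1 (-1.18 against -1.72 to -1.64), Dlk1 (-0.64 against -0.02 to 0.09), Vcam1 (4.73 against 3.99 to 4.02), Bmp2 (0.24 against -0.22 to -0.16), Clec7a (5.33 against 4.82 to 4.89) and Irf7 (2.85 against 2.20 to 2.28). It also stood apart for the list means of matrix proteases (0.50 against -0.16 to -0.11), lymphocyte genes (0.56 against -0.51 to -0.36) and thyroid, salivary gland and epithelium genes (-0.36 against -0.17 to -0.14). Itgax was 4.57 on miR-126+/+ 4, against 4.00 to 4.07. Array miR-126-/- 1 stood apart for the muscle genes Myh7 (-1.24 against -3.28 to -2.95), Tnnc1 (-0.85 against -4.01 to -3.57) and Tnnt1 (3.88 against -0.28 to 0.42), for Gpihbp1 (2.88 against 3.24 to 3.27) and for Mpo (-1.72 against -2.67 to -2.53). On miR-126-/- 2, Cercam was -0.52 against -0.86 to -0.80. On miR-126-/- 3, Baiap2l2 was -1.57 (-1.45 to -1.43 elsewhere), Sh3gl3 was -0.78 (-0.65 to -0.63) and the macrophage list mean was 0.21 (-0.17 to -0.12). On miR-126-/- 4, Lctl was 0.47 against -0.23 to -0.14, and the cell cycle list mean was 0.13 against -0.05 to -0.03.

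Of the 35 splits of the 8 arrays into 4 and 4, the real split alone (1) gave as many as 23 called genes. The highest other split gave 6. This does not exclude chance, since the probe filter used the real genotypes. It admits genes well above background in only 1 of them, which favours the real split. With probes above background on all 8 arrays, a filter blind to genotype, the real split called 6 genes. The other splits were not run with that filter. The smallest share that the splits can give is 1 of 35, and the real split also divides the arrays by slide row. Chance was not excluded for the other counts either. As many as 276 genes of at least 2-fold fitted difference came from 3 splits, with 345 in the highest other split. As many as 2426 genes at an unadjusted p under 0.05 also came from 3, with 2760 in the highest other. For both counts the splits above the real split put miR-126+/+ 2 and miR-126-/- 1, the arrays highest in skeletal muscle genes, on the same side. At least 4 lists passed in 34 splits, and the highest other split gave 13. An odds ratio of at least 1.41 near Egfl7 came from 3 splits, with 1.66 in the highest other split.

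Adipocyte, oxidative phosphorylation and endothelial genes were higher in miR-126-/- arteries. For the adipocyte genes the mean was 1.28 under quantile normalization and 1.30 in the main setting, so the choice between these scalings does not account for it. This is a weak test of array scaling, since the scalings barely differed: the median difference over all genes was -0.005 and 0.008. Whether a larger share of fat around the miR-126-/- arteries accounts for the adipocyte genes cannot be told: 69.0% of them moved with the other members within 2 standard errors, between the 80% set for a common factor and the 50% set against it (bounds kept from a first form of the test, distance from the list's median, which was dropped after its result of 96.6% because 21 of the 24 lists met its 80%). Whether fat accounts for the other lists cannot be told either: with the adipocyte mean as a covariate the mean of oxidative phosphorylation went from 0.309 ± 0.093 to 0.0790 ± 0.133 and that of endothelial genes from 0.310 ± 0.102 to 0.238 ± 0.196 (SE over mice), and the adipocyte mean is so close to genotype that this covariate also removes part of any genotype difference. The slide row of the arrays and an effect of miR-126 on fat or vessel cells stay open and were not tested.

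Called genes lay close together on chromosomes 2, 10 and 11 (Card9 with Cercam 3.53 Mb apart, Casp14 with Med16 1.18 Mb apart, Hoxb7 and Hoxb8 with Tob1 and Krtap1-4). As many pairs came from a share of 0.0043 of random gene sets, and of 0.0332 with Hoxb8 left out. This test was chosen after the closeness was seen in the same genes, so it does not exclude random placement. Every pair but Casp14 with Med16 includes a gene at the highest adjusted p in limma among the called genes, 0.04998. Strain haplotypes that differ between the genotypes may account for the closeness, and for the agouti gene among the called genes, as the mice had a mixed background. As many pairs among the 200 lowest p-values came from 5 of 35 splits (168 pairs in the real split, 297 in the highest other). This outcome had been set beforehand to count against haplotypes. It was later read as undecided, since the 200 genes are a wider set than the called genes and mice of a mixed background may differ in other splits too. A strain variant under the probe could account for second probes that differed less for 75% of the named called genes with more than 1 probe (3 of 4, or 4 of 6 with the unnamed ones, against 14 of the 40 with more than 1 probe among the next 200 genes, Fisher's exact p = 0.282 and 0.191), but splice forms would do the same. Together with the odds ratio of 1.41 near Egfl7 (Fisher's exact p = 0.0866), these values leave random placement, strain differences and an effect of miR-126 open.

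Abundant genes such as Sdha were far lower on array miR-126-/- 4 than on all others. A local defect of that array is a likely cause, since 96.9% of its low spots lay in a rectangle that held 1.27% of its bright spots. No other array had a low spot there, although miR-126+/+ 3 had 45 low spots elsewhere. No biological explanation was tested.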

How the results depend on the processing

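The alternatives without the least similar arrays, without the arrays highest in skeletal muscle genes and without the dim area were chosen only after the data were seen. Over lists, where the direction is that of the test, 536 values kept their direction and side of the threshold, 20 no longer passed, 23 newly passed and 43 reversed; over named genes the numbers were 2401, 238, 12 and 26. All 17 named called genes kept their sign, and Med16 stayed past the threshold in 19 of 23 alternatives, Card9 in 15 of 23, Casp14 in 14 of 22 and Hoxb7 in 13 of 22, against 4 of 22 for Msmp, Krtap1-4 and Fam228a. The adipocyte call held in 23 of 25 alternatives (means 1.03 to 1.55), oxidative phosphorylation in 23 of 26 and the endothelial call in 24 of 26. These 3 calls were lost with an estimated correlation (adjusted p = 0.762, 0.762 and 0.837) and with fry (0.122, 0.122 and 0.177), and oxidative phosphorylation also with the adipocyte covariate (0.352); their lowest adjusted p over the alternatives were 1.26e-26, 1.09e-19 and 6.73e-10. Signal over background limits the genes that are dim in a genotype, whose fitted differences are not measured sizes. Where no construction is named, the cause was not tested. Predicted miR-126 sites were not run, and the adipocyte and skeletal muscle lists gave no value with themselves as covariates.

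The number of called genes (23) was 24 under normexp (12 of them among the 23), 11 under quantile normalization (11), 25 with the 75th percentile over probes above background (22), 12 with the deposited table (12), 9 with no filter (6), 6 with probes above background on all arrays (6), 10 with the mean of probes (10), 12 probes with every probe on its own (11), 27 with an intensity trend (19), 73 with array weights (23), 5 with the skeletal muscle covariate (5), 0 with the adipocyte covariate, 8 without the least similar arrays (4), 0 without the arrays highest in skeletal muscle, and 0 to 59 with single arrays left out (0 to 17). Without the dim area it was 30, all 23 among them, with Lhx3 at an adjusted p of 0.0486 (0.0301 to 1.0 over its alternatives). With the replicate number, which is also the slide column, as a block, limma called 0 genes (2196 at an unadjusted p under 0.05). Whether the numbers pair the mice cannot be told. Deviations of same-numbered mice correlated at 0.205, -0.284, -0.0447 and 0.00741. Not every array correlated best with its own number (miR-126+/+ 2 with miR-126-/- 1, 0.403). Those arrays are the highest in skeletal muscle genes, and such variation could mask a pairing. The count of fitted differences of at least 2-fold (276, with 203 higher and 73 lower) was 149 under normexp (125 and 24) and 470 with no filter (268 and 202). It was 165 with probes above background on all arrays and 156 with the adipocyte covariate. The odds ratio near Egfl7 passed under normexp (1.57), the 75th percentile over probes above background (1.52) and no filter (1.74), with p from 0.00306 to 1.0 over its alternatives, and was 0.894 with the adipocyte covariate. The number of lists past the threshold (4) was 0 with an estimated correlation, 0 with fry, and 3 to 7 with single arrays left out, with 7 without miR-126-/- 1.

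A list mean near 0 need not turn with its test: the mean kept its sign in 11 of the 43 reversals and changed sign in 48 cases where the test did not turn, such as interferon with the adipocyte covariate (0.041 to -0.144). With that covariate the tests of these lists reversed, with means of: extracellular matrix 0.258, matrix proteases 0.143, osteochondrogenic 0.047, erythroid 0.359, ERK feedback 0.095, immediate early 0.092, heat shock 0.263 and thyroid -0.017. So did Mmp19 (0.045), Timp4 (-0.62), Ctsk (0.054), Cd36 (-0.11), Ppbp (0.24), Mpo (0.082), Ahsp (0.26), Ifi27 (-0.087), Dhx58 (-0.16), E2f1 (0.11), Dusp4 (-0.13), Ddit3 (0.013), Srebf1 (-0.059), Ugt8a (-1.26), Amy1 (-0.52) and Epcam (-0.23). Without the least similar arrays the tests of extracellular matrix (0.043), matrix proteases (0.112), neutrophil and platelet (0.110), cytokine (0.190), ERK feedback (0.061) and heat shock genes (0.074) reversed. Without the arrays highest in skeletal muscle, cell cycle (-0.047), Slc4a1 (-0.065) and Tnnt1 (-0.16) reversed. With array weights osteochondrogenic (0.037) and cytokine genes (0.151) reversed, and with the mean of probes Sparc (0.079). The interferon test turned from down to up under normexp (0.050), no filter (0.041), array weights (0.196), fry (0.041) and without the arrays highest in skeletal muscle (0.102), and the ERK feedback test with no filter (0.0050).

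Leaving out single arrays gave list means from -0.102 to 0.120 for matrix proteases, -0.100 to 0.052 for osteochondrogenic, -0.118 to 0.126 for neutrophil and platelet, -0.308 to 0.145 for erythroid, -0.148 to 0.195 for cytokine, -0.084 to 0.108 for interferon, -0.087 to 0.140 for cell cycle, -0.111 to 0.105 for heat shock, -0.096 to 0.075 for cholesterol, -0.57 to 1.03 for skeletal muscle and -0.67 to 0.37 for nerve genes. Single genes ran from -0.049 to 0.52 (Slc4a1), -0.50 to 0.14 (Ahsp), -0.10 to 0.95 (Tnnc1), -0.086 to 1.64 (Myl1) and -0.36 to 1.03 (Tnnt1).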

Other observations

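The genes in this part were chosen after their values were seen, and no further tests were made on them. Ucp1, the uncoupling protein of brown fat, gave 2.19 ± 1.01 (log2 ± SE, n = 4 each, adjusted p = 0.528) and Cidea 1.90 ± 0.43 (adjusted p = 0.195). Cpt1b, which brings fatty acids into mitochondria, gave 1.86 ± 0.26 (adjusted p = 0.0577), Cox8b 1.71 ± 0.51 (adjusted p = 0.305) and Cox7a1 1.60 ± 0.48 (adjusted p = 0.302). None of the 5 passed the test in the main setting, and of these Cpt1b alone passed in any alternative (4 of 23, adjusted p from 0.0137 to 1.0). Each was higher in miR-126-/- arteries under all 3 other scalings and background corrections, but with the adipocyte list mean as a covariate the values of Ucp1, Cidea, Cpt1b, Cox7a1 and Cox8b were 1.18, 0.39, 1.24, 0.21 and -0.058. No other of the 23 alternatives changed the sign of any of them. Ucp1 and Cidea are members of the adipocyte list, so with that covariate they were adjusted for a mean that includes them, and part of their fall is built in.

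Further genes of the HoxB cluster were measured beside the called genes Hoxb7 and Hoxb8. Hoxb6 gave 1.74 ± 0.35 (adjusted p = 0.169) and Hoxb5 1.66 ± 0.38 (adjusted p = 0.203), while Hoxb4, Hoxb3 and Hoxb2 gave 0.24, 0.08 and 0.12. Over the alternatives Hoxb6 ran from 0.84 to 2.13 and Hoxb5 from 1.10 to 2.18, and neither changed sign. Gsn, the actin-severing protein gelsolin, gave -0.75 ± 0.10 (adjusted p = 0.0563; 0.0279 to 0.922 over its alternatives).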
